A study of Homo sapiens with 42 samples.

How the data were processed

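Total RNA of Hep3B cells was measured on 42 arrays, 1 per culture, with 21 arrays from CM and 21 from NCM. Per the labels, cultures were challenged in pairs prepared from a shared batch of trypsinized cells, and this was repeated in 3 independent experiments. The deposited values are linear intensities, not log values, with 1 value per probe and array and a mean over all probes near 1 on every array. The array type, scanner, background step and scaling step are not given in the sources used here. Slightly negative values occur, at most 2.12% of the probes of an array. The SD of the arrays' medians was 0.31 and that of their interquartile ranges 0.36 on the log2 scale, above the 0.1 set as the limit, so the arrays were quantile normalized. Normalization was done on the linear scale, then values below the common 1st percentile, 0.0813, were set to it and log2 was taken. The 1st percentile of single arrays can lie below 0, so the floor could not be taken on each array before the normalization, as had been planned.

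Tests used R 4.3.3 with limma 3.58.1, and plots used Python with matplotlib 3.10.9. The linear model had 1 term per pair and 1 CM effect per time, on all 42 arrays, with 14 residual degrees of freedom and a prior SD of 0.31 on 6.26 prior degrees of freedom. Tests were moderated, two-sided and adjusted by Benjamini-Hochberg over the 13824 probes of a contrast, with a threshold of 0.05. An F test covered the 6 times after T0, and another compared the times in the 21 NCM arrays with no block. The pairs come from the labels. They were also checked in the values: deviations of the CM and NCM array of a pair from their group means correlated at 0.308 to 0.754, over the limit of 0.1 in 21 of 21 pairs.

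Gene names came from the array annotation and were matched by Entrez ID to a gene table of assembly GRCh38.p14, used for names only. Of 7336 probes with 1 gene, 7322 matched and 0 symbols were updated, giving 5631 genes, 1128 of them with more than 1 probe. A gene was represented by its probe with the highest mean log2 value. The rule for named genes took at 1 h, 3 h, 6 h and 16 h up to 10 genes in each direction past the threshold with 3 pairs in the same direction, and up to 3 at T0, 15 min and 30 min. For NCM over time it took up to 5 genes. Where none passed it took the 3 with the smallest unadjusted p, given as values. It added 36 fixed genes and list members past the threshold. Members that passed only when adjusted over the list alone, second probes and the genes in the plots outside that rule were picked after their values were seen.

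The 37 gene lists, 7 of them markers of other cell types, were tested by camera with a preset correlation of 0.01 on 1 probe per gene where at least 5 genes were measured, which held for 35 lists and gave 245 tests over the 7 times, adjusted together. The lists of the mean over 3 h, 6 h and 16 h were adjusted by themselves. Camera with an estimated correlation and fry were run beside it, and the results of fry are not given here. The design, lists, fixed genes and most alternatives were chosen before the data were examined. The means over 3 times, neighbour centring, array weights, leaving out the least correlated pairs, the array cluster as a block and leaving out probes with copied values were chosen after seeing the data. Copied values are values equal to those of another probe on all 6 arrays of a time, with no tolerance.

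The alternatives were no block, values as deposited, median centring, leaving out the dimmest 25% or 50% of probes and a floor at the 10th percentile. Others were each time fitted alone, an intensity trend with robust spread, probes of a gene averaged, a change of at least 1 and the change minus that at T0. Each replicate was also left out in turn. For probe counts and named genes of CM against NCM, this dropped its pairs at the tested times only. For the gene lists and NCM over time, it dropped the replicate at all times. Neighbour centring took probe numbers as places on 36 grids of 16 by 24 wells, an assumption from the numbering, and subtracted on each array the mean deviation of the neighbouring probes. Groupings of arrays came from hierarchical clustering into 4 clusters. Other splits of the arrays numbered 10 per time, or 100 drawn for tests over more arrays. No array or probe was left out of the reported fit. The steps were tested on simulated data: with changes of known size added at 16 h among 13824 probes, 2 of 50 were recovered at a log2 change of 0.5, 19 at 1, 36 at 1.5 and 46 at 2, with 2 unchanged probes called at 16 h and 0 at T0.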

Results

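Messenger RNA was measured by array in Hep3B cells, a human hepatoma line, cultured with CM, which the labels describe as enriched in pro-inflammatory cytokines, or with the control medium NCM. The question given in the labels is how mRNA abundance changed over time in CM against NCM. The 42 arrays form 14 groups of 3, with both media at T0, 15 min, 30 min, 1 h, 3 h, 6 h and 16 h. Each of 3 experiments gave 1 CM and 1 NCM culture per time from a shared batch of cells, so each time has 3 pairs. Every array holds 13824 probes, of which 7336 name 1 gene, 576 name several genes and 5912 name none. The mean intensity per array lay between 0.999 and 1.00, and the median intensity per array between 0.354 and 0.807. The number of arrays limits the precision of every value. All changes are CM minus NCM on the log2 scale, with SE from limma, and a gene is represented by its brightest probe unless a probe number is given. The SE and p rest on a moderated spread pooled over the pairs of all times. They do not measure the spread of the 3 pairs of a time alone.

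**Figure D1:**
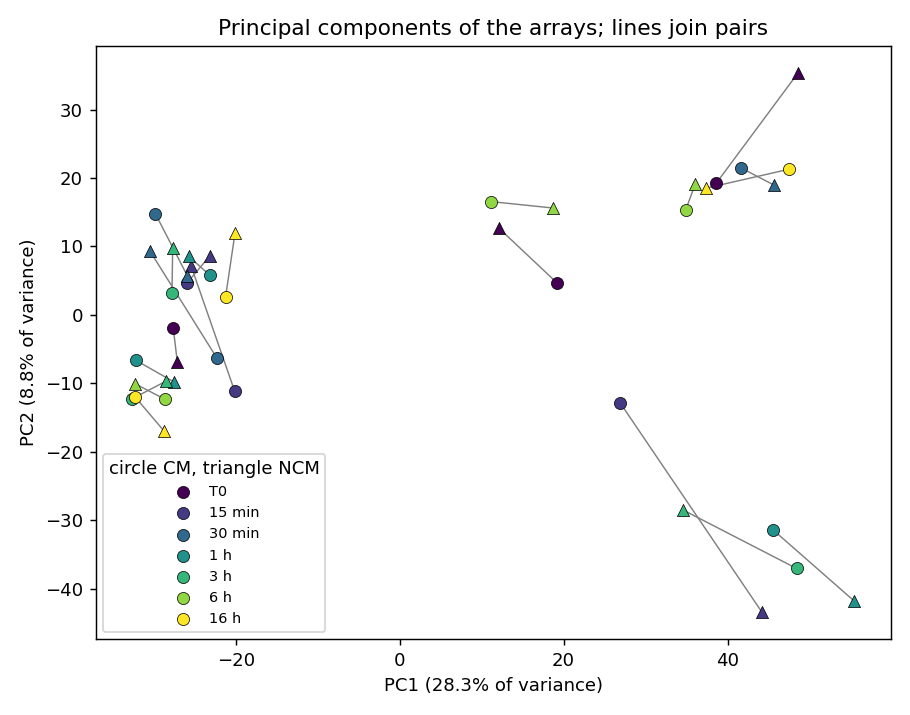
Arrays on the first and second principal components of the log2 values (28.3% and 8.80% of the variance), coloured by time, with circles for CM and triangles for NCM. Lines join the CM and NCM array of each of the 21 pairs, and both arrays of every pair lie in the same array cluster.

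At 16 h, CFB, the gene of complement factor B (probe 2983), rose 2.77-fold in CM (log2 change 1.47, SE 0.22, n = 3 pairs, adjusted p = 0.0177, higher in 3 of 3 pairs). Its mean log2 intensity was 0.20 in CM and -1.27 in NCM, and the pair differences had an SD of 0.61. At T0 CFB had 0.41 (SE 0.22, adjusted p = 1.00, higher in 3 of 3 pairs), and for the change minus the change at T0 limma called 0 probes at 16 h. ORM1, which encodes the acute phase protein orosomucoid, had a change of 1.23 (SE 0.23, n = 3 pairs, adjusted p = 0.103, higher in 3 of 3 pairs), and its other probes had 1.16 and 1.38. CCL20, a chemokine gene, had 1.29 and ITIH4, an inter-alpha-trypsin inhibitor heavy chain gene, had 0.62; both passed only when adjusted over the list alone. Among further acute phase genes, FGG had 0.62, FGB 0.56 with 0.03 on its other probe, and HP 0.54, while HPX, of the list of acute phase proteins that rise, had -0.48 and was lower in 3 of 3 pairs. TTR had -0.30, AFP -0.31, ALB -0.04 and CRP -0.08, with 0.14 and 0.64 on the other probes of CRP, and none of these genes or probes passed the threshold. CRP probe 5788, with 0.64 at 16 h, had 1.12 at 6 h (higher in 3 of 3 pairs) and 0.71 in the mean of 3 h, 6 h and 16 h (higher in 8 of 9 pairs), neither past the threshold, against -0.07 and -0.05 on the brightest CRP probe. limma called 1 probe, which was CFB, with 658 probes at an unadjusted p under 0.05 against 691.2 from chance alone. The other probes of CFB had 0.47 and 0.30, each higher in 3 of 3 pairs and neither past the threshold, and the mean of the gene's probes had 0.74 with an adjusted p of 0.351. Over its alternatives the adjusted p of CFB ranged from 0.00333 to 0.750, with 0.750 and 0 probes called without the pairs as a block, 0.258 with the values as deposited, 0.313 without replicate 2 and 0.211 without replicate 3.

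The list of acute phase proteins that rise, 21 genes measured, had a median change of 0.13 at 16 h, with 11 genes above 0. In it 1 gene rose over all probes, CFB, and 3 passed when adjusted over the list alone, CFB, ORM1 and ITIH4. At 6 h its median was 0.15, with 15 genes above 0, among them CFB at 0.83 and FGG at 0.78, and camera called the list higher (adjusted p = 0.0333). That call had an adjusted p = 0.814 with an estimated correlation, 0.479 without replicate 1 (median 0.07), 0.108 without replicate 2, 0.0800 without replicate 3 and 0.126 with neighbour centring, and was kept with the mean of all probes of a gene (median 0.23), in a range over its alternatives of 0.00246 to 0.814. At 6 h 0 genes of the list passed over all probes by limma, and 1 passed when adjusted over the list alone, CFB. The list of acute phase proteins that fall, 19 genes measured, had a median of -0.09 at 6 h and -0.05 at 16 h and was called at no time. Of the 36 genes fixed in advance, 30 were measured and 1, CFB, passed at any single time; 8 had an unadjusted p under 0.05 at 6 h or 16 h.

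**Figure D2:**
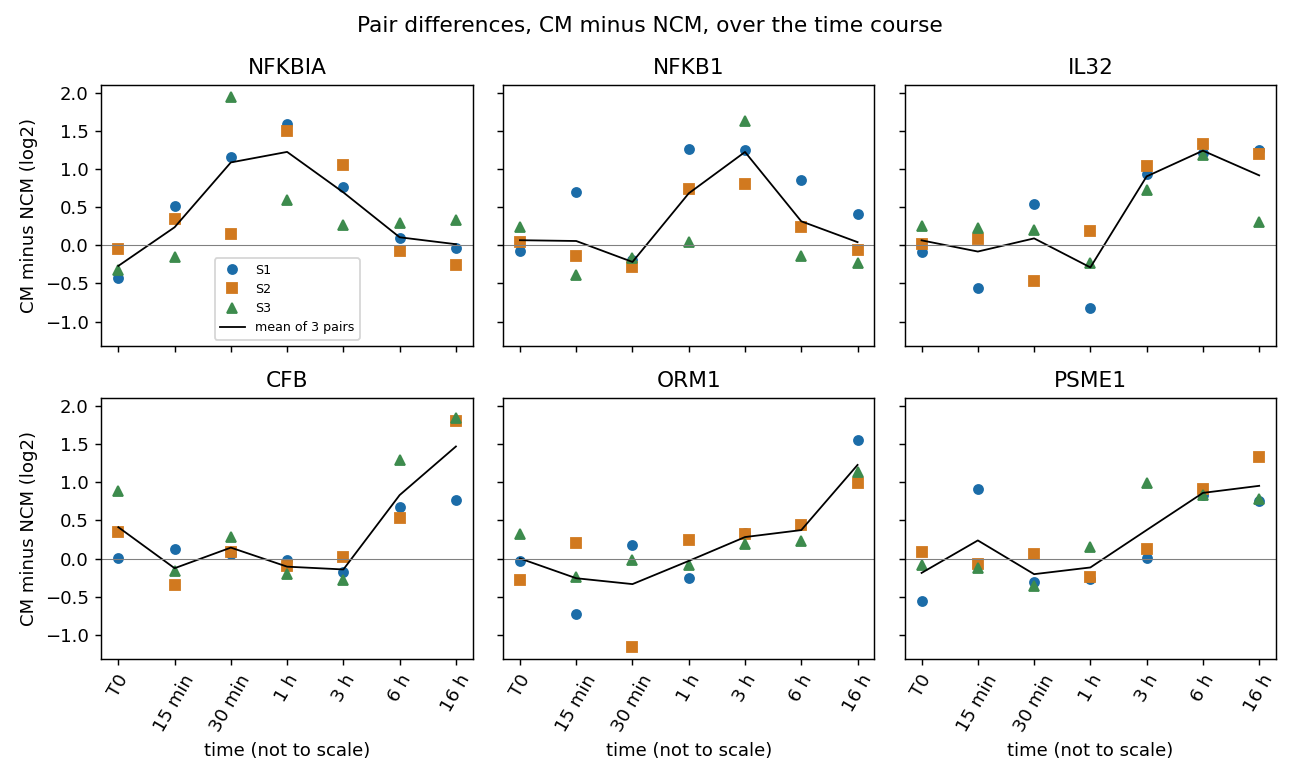
Change in CM against NCM (log2) at each time for NFKBIA, NFKB1, IL32, CFB, ORM1 and PSME1, with 1 point per pair in experiments S1, S2 and S3 and a line through the mean of 3 pairs. NFKBIA has a mean of 1.09 at 30 min and 1.23 at 1 h, and CFB and ORM1 have 1.47 and 1.23 at 16 h.

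At 6 h, IL32, a cytokine gene, had the smallest unadjusted p (change 1.24, SE 0.23, n = 3 pairs, adjusted p = 0.232, higher in 3 of 3 pairs), with an SD of 0.08 between pairs. PSMB10, a subunit of the immunoproteasome, had 1.09 (SE 0.22) and PSME1, a proteasome activator subunit, 0.86 (SE 0.23), each higher in 3 of 3 pairs. The change of PSMB10 was 0.65 without replicate 1 and 0.56 with the values as deposited. Both belong to the antigen presentation list, 14 genes measured with a median of 0.06, in which 2 genes passed when adjusted over the list alone and 0 over all probes by limma. ABCA1, a cholesterol exporter, had 1.11, PLAT, tissue plasminogen activator, had 0.72, and PDXDC2P-NPIPB14P had 0.91 (0.59 with the values as deposited), all higher in 3 of 3 pairs and none past the threshold over all probes. limma called 0 probes at 6 h, with 520 at an unadjusted p under 0.05, and 0 without the block. The apoptosis list, 10 genes measured with a median of 0.23, was called higher by camera (adjusted p = 0.0491), with an adjusted p = 0.628 with an estimated correlation and 0.119 without the block. It was lost under each of its alternatives, in a range of 0.0509 to 0.704, and its median was 0.13 with the values as deposited. In it 0 members passed by limma over all probes or when adjusted over the list alone. The members with the largest changes were BCL2L2 at 0.70, an antiapoptotic BCL2 relative, FAS at 0.66, a death receptor, and BIRC2 at 0.62, an inhibitor of apoptosis.

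At 3 h, NFKB1, which encodes the p105 and p50 subunits of NF-kappaB, had 1.22 (SE 0.25, n = 3 pairs, adjusted p = 0.462, higher in 3 of 3 pairs). Its other probes had 0.18 and 0.16. IGFBP1, an insulin-like growth factor binding protein gene, had 1.38 (SE 0.29) with 0.31 on its other probe, and IL32 had 0.90 (SE 0.23), which was 0.58 with neighbour centring. limma called 0 probes at 3 h, with 450 at an unadjusted p under 0.05, and 0 without the block. The list of NF-kappaB feedback and targets, 14 genes measured, had a median of 0.22 with 11 genes above 0 and was called higher by camera (adjusted p = 0.0296). That call had an adjusted p = 0.628 with an estimated correlation, 0.0914 with neighbour centring, 0.136 without replicate 1 and 0.0987 without replicate 2, in a range over its alternatives of 0.00957 to 0.628, and it was also lost without replicate 3. NFKB1 was the 1 member that passed when adjusted over the list alone, with 0 over all probes by limma. The metallothionein list, 5 genes measured, was called higher (median 0.38, adjusted p = 0.0491), with an adjusted p = 0.814 with an estimated correlation and 0.119 without the block; it was also lost with neighbour centring, with the mean of all probes of a gene and without each replicate, in a range of 0.0116 to 0.814. At 3 h MT2A and MT1G carry identical values on all 6 arrays, both at 0.38, and so do MT1E and MT1X, both at 0.37, so the 5 genes rest on 3 distinct sets of values. Without probes that carry copied values the metallothionein median was 0.12, over too few genes to test.

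At 1 h, NFKBIA, the NF-kappaB inhibitor gene that NF-kappaB itself induces, had 1.23 (SE 0.27, n = 3 pairs, adjusted p = 0.569, higher in 3 of 3 pairs). CXCL2, a chemokine gene, had 0.97, CEBPD, a transcription factor gene of the acute phase response, 1.14, and MYC 0.92, all higher in 3 of 3 pairs. EIF3E, a translation initiation factor gene, had -0.78 (SE 0.17), and ACTG1, gamma actin, had 1.32 (SE 0.28) on 1 probe and -0.23 on its other probe. limma called 0 probes at 1 h, with 605 at an unadjusted p under 0.05, and 0 without the block. Camera called the list of NF-kappaB feedback and targets higher (median 0.17, 11 of 14 genes above 0, adjusted p = 0.0365). That call had an adjusted p = 0.628 with an estimated correlation, 0.0837 with the values as deposited (median 0.06), 0.149 with the mean of all probes of a gene, 0.418 without replicate 2 and 0.111 without replicate 3 (median 0.10), in a range over its alternatives of 0.00714 to 0.628. It also called the STAT3 pathway and targets higher (median 0.15, 16 of 20 genes above 0, adjusted p = 0.0365), with an adjusted p = 0.628 with an estimated correlation, 0.0760 with the mean of all probes of a gene, 0.338 without replicate 2 (median 0.09) and 0.147 without replicate 3, in a range of 0.00194 to 0.628. Adjusted over the list alone, NFKBIA passed in the first list and CEBPD and MYC in the second, with 0 members over all probes by limma. CXCL2 passed within the chemokine list when adjusted over the list alone.

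At 30 min NFKBIA had 1.09 (SE 0.27, n = 3 pairs, adjusted p = 0.997, higher in 3 of 3 pairs), with an SD of 0.90 between pairs and a change of 0.66 without replicate 3. ATF3, an immediate early transcription factor gene, had 0.96, and both genes passed when adjusted over the list alone. ZBTB33 had 0.96, which was 0.14 with the values as deposited, and DNAJA4 had 0.84. At 15 min the genes with the smallest unadjusted p were BDH1 at 0.81, DAPK1 at 0.89, which was 0.48 with the values as deposited, and TMEM126B at -1.02. limma called 0 probes at 15 min, with 492 at an unadjusted p under 0.05, and 0 at 30 min, with 485, and 0 at both without the block. The self-test added changes at 16 h to simulated values, made of fitted means and independent noise. It recovered 19 of 50 probes at a log2 change of 1 and 36 of 50 at 1.5. In such values changes near 1 were often below detection with 3 pairs. They lack the correlation between neighbouring probes that the arrays show, so recovery in the real values can differ.

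Ribosomal protein genes, 53 measured, were called lower by camera at 15 min (median -0.17, adjusted p = 0.0333), 30 min (median -0.20, adjusted p = 0.0333) and 1 h (median -0.20, adjusted p = 0.00202). With an estimated correlation the adjusted p was 0.897, 0.897 and 0.847, the estimated correlation among the 53 genes being 0.287. RPS3 had -0.56 and RPS4X -0.60 at 30 min, and 0 of the 53 genes passed by limma over all probes or when adjusted over the list alone at any of these times. The same list had a median of -0.12 at T0 and 0.14 at 16 h. With the values as deposited the list was not called at 15 min or 1 h (adjusted p = 0.290 at both, in ranges over its alternatives of 0.00107 to 0.897 and 7.5e-06 to 0.847). Without replicate 3 the call was lost at all 3 times, with medians of -0.02 at 15 min, -0.22 at 30 min and -0.12 at 1 h. Without replicate 2 the median was -0.16 at 15 min and -0.06 at 30 min, both calls lost, and -0.36 at 1 h, with the call kept. Without replicate 1 it was -0.31 at 30 min, with the call kept.

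**Figure D3:**
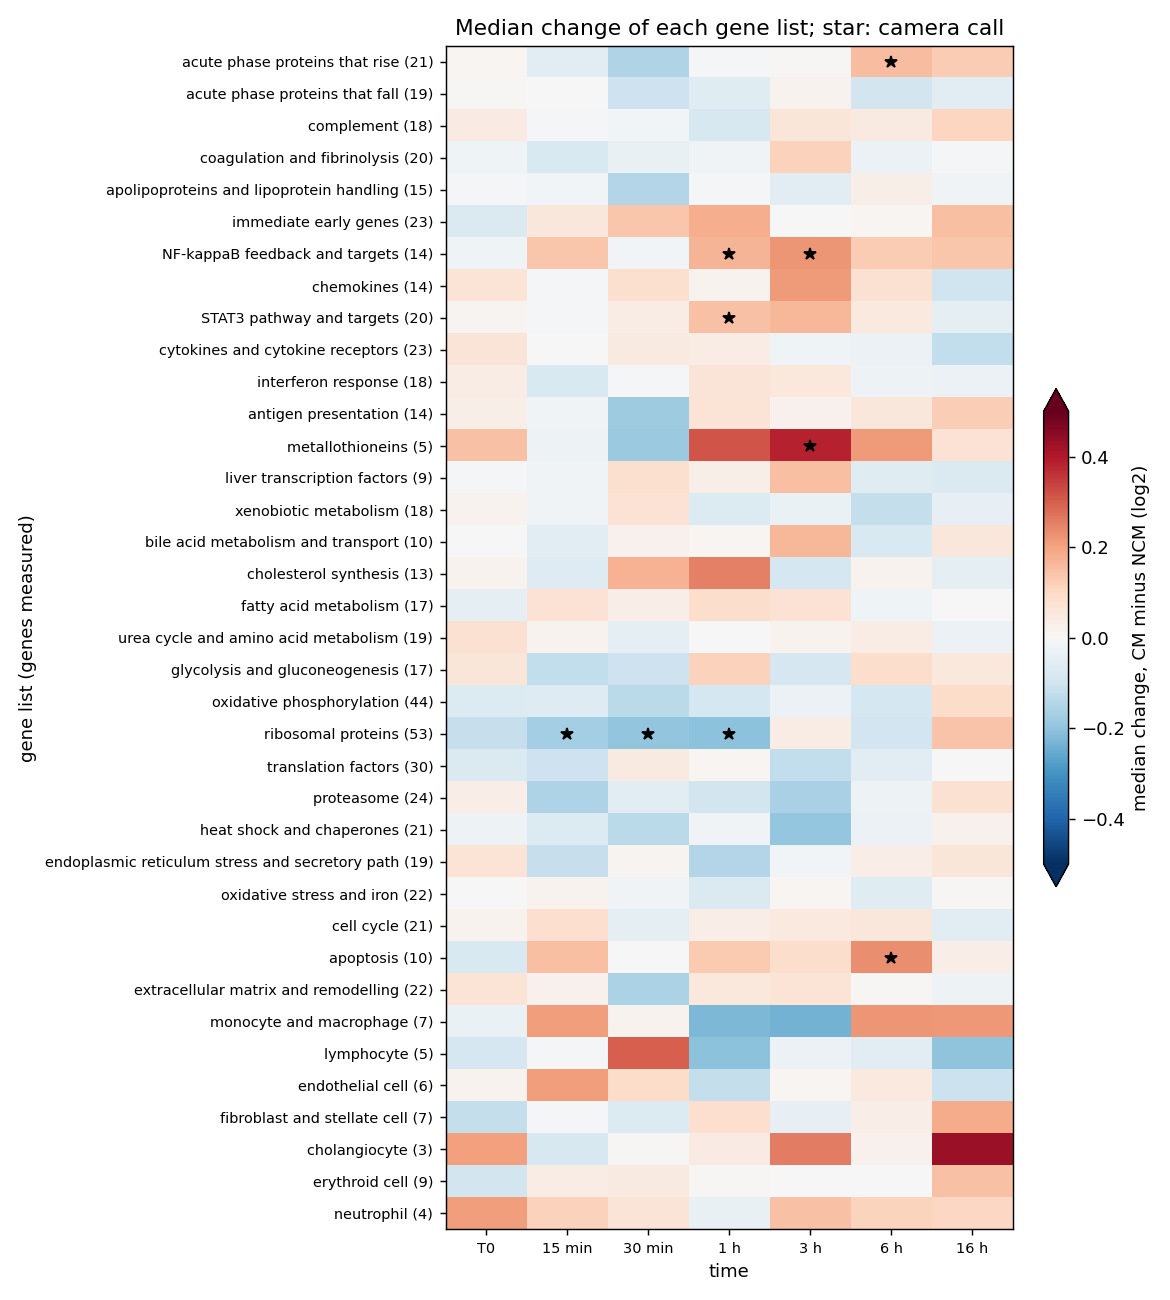
Median change of each gene list in CM against NCM (log2, colour) at each time, with the number of genes measured in brackets and a star where camera called the list. The 9 stars lie in 6 lists: ribosomal proteins at 15 min, 30 min and 1 h, NF-kappaB feedback and targets at 1 h and 3 h, STAT3 pathway and targets at 1 h, metallothioneins at 3 h, and acute phase proteins that rise and apoptosis at 6 h. Each of the 9 calls was lost with an estimated correlation, and each was lost without replicate 3, left out at all times.

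Averaged over 3 h, 6 h and 16 h, a contrast chosen after seeing the data, IL32 rose by 1.02 (2.03-fold, SE 0.13, n = 9 pairs, adjusted p = 0.00304, higher in 9 of 9 pairs). The labels do not say whether 1 experiment number means the same batch of cells at different times. The 9 pairs of a mean over 3 times come from 3 experiments, and the fit treats them as independent. The SE and adjusted p of such a mean can therefore overstate the replication. PSME1 rose by 0.73 (SE 0.13, adjusted p = 0.0470, higher in 9 of 9 pairs), and CFB by 0.72 (SE 0.13, adjusted p = 0.0418, higher in 7 of 9 pairs). Probe 8544 of IL1R1, the interleukin-1 receptor gene, rose by 0.74 (adjusted p = 0.0137, higher in 9 of 9 pairs), while the brightest IL1R1 probe had 0.052 (adjusted p = 0.976). limma called 6 probes, all higher, the other 2 being a probe without a gene name and a probe naming 2 genes. Camera called NF-kappaB feedback and targets (median 0.25, 13 of 14 genes above 0, adjusted p = 0.000244), acute phase proteins that rise (median 0.07, adjusted p = 0.0103) and complement (median 0.11, adjusted p = 0.0468). With an estimated correlation the adjusted p was 0.0571, 0.275 and 0.275. Complement had a median of 0.03 without probes that carry copied values (adjusted p = 0.207) and 0.04 with neighbour centring (adjusted p = 0.192), and was lost without each replicate, in a range over its alternatives of 0.00757 to 0.275. The acute phase call was lost without replicate 2 (median 0.03, adjusted p = 0.118) and without replicate 3 (median 0.14, adjusted p = 0.0517), in a range of 8.6e-07 to 0.275; its median was 0.11 without replicate 1 and 0.19 with the mean of all probes of a gene, with the call kept in both. The NF-kappaB median was 0.14 with the values as deposited, with the call kept there and without each replicate. In the acute phase list 5 genes were higher and 1 lower when adjusted over the list alone, CFB, ORM1, FGG, FGB and ITIH4 against PTX3, with CFB past the threshold over all probes. Adjusted over the list alone, NFKB1 passed in the NF-kappaB list and CFB in the complement list. In the blocked fit 826 probes had an unadjusted p under 0.05; without the block limma called 0 probes, and without replicate 1 or replicate 2 it also called 0. Without replicate 1, 2 and 3 the adjusted p of IL32 was 0.149, 0.238 and 0.0207, in a range over its alternatives from 0.000386 to 1.00, and PSME1, CFB and the IL1R1 probe passed in none of the 3. With the mean of all probes of a gene CFB had 0.36 (adjusted p = 0.521) and IL1R1 0.40 (adjusted p = 0.371). With the values as deposited the adjusted p was 0.782 for CFB, 0.342 for PSME1 and 0.991 for the IL1R1 probe, in ranges over their alternatives of 0.0155 to 0.948, 0.0348 to 1.00 and 0.145 to 0.991. For the change minus the change at T0 limma called 0 probes. Averaged over 15 min, 30 min and 1 h, limma called 0 probes, with 967 at an unadjusted p under 0.05 and 0 without the block; NFKBIA had 0.85 (SE 0.15, adjusted p = 0.267, higher in 8 of 9 pairs), PDIA3 -0.65 and RPS3P3 -0.53.

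At T0, the background of the other comparisons, AVPR1A, a vasopressin receptor gene, had -1.66 (SE 0.33, n = 3 pairs, adjusted p = 0.716), CLIP1 had -1.31 (-0.70 with neighbour centring) and PIP5K1A had -0.92 (-0.60 without replicate 3), each lower in 3 of 3 pairs. limma called 0 probes, with 700 at an unadjusted p under 0.05, and 0 without the block. The value of AVPR1A at T0 was larger in size than the 1.47 of CFB at 16 h, with a larger SE. No list was called at T0.

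The changes at adjacent late times were compared directly. limma called 0 probes between 1 h and 3 h, with 442 at an unadjusted p under 0.05, 0 between 3 h and 6 h, with 419, and 0 between 6 h and 16 h, with 319. The test for a change at any time after T0 called 0 probes, with 414 at an unadjusted p under 0.05. All of these counts were also 0 without the block. The rise of CFB at 16 h is therefore not shown to differ from its change of 0.83 at 6 h, and the change in NFKBIA at 1 h is not shown to differ from that at 3 h.

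In NCM alone, 2 probes differed between times by limma's F test, with 231 at an unadjusted p under 0.05. The count was 0 without replicate 1, 0 without replicate 2, 0 without replicate 3, 0 without the pairs of the least correlated arrays, 1 with the values as deposited, 1 with median centring of each array only and 1 without the probes with copied values. STAT5B probe 5869 (adjusted p = 0.0159) had a mean of 1.45 at 1 h and -1.37 at 30 min. STAT5A probe 10003, which is not the brightest probe of its gene (adjusted p = 0.000865), had a mean of 2.94 at 30 min and -1.02 over the other times. Both genes encode signal transducers of the STAT family. At T0, 15 min, 3 h and 16 h, but not at 30 min, the values of STAT5A probe 10003 equal those of STAT5A probe 1178 on all arrays. At 1 h and 6 h, with values not equal to another probe's, its NCM means were -2.63 and -2.47. The mean of -1.02 and the F test of this probe therefore mix 2 sources of values. The changes of the other probes, at 30 min for STAT5A and at 1 h for STAT5B, were at most 0.20.

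The 29 remaining lists with at least 5 measured genes were called at no single time, the smallest adjusted p being 0.0875 for chemokines at 3 h. Their median changes at 16 h, where CFB rose, were 0.11 for complement, -0.0043 for coagulation and fibrinolysis, -0.02 for apolipoproteins and lipoprotein handling, 0.15 for immediate early genes, -0.10 for chemokines, -0.12 for cytokines and cytokine receptors, -0.03 for interferon response and 0.12 for antigen presentation. Among the metabolic and liver lists the medians at 16 h were -0.07 for liver transcription factors, -0.04 for xenobiotic metabolism, 0.06 for bile acid metabolism and transport, -0.05 for cholesterol synthesis, 0.00030 for fatty acid metabolism, -0.03 for urea cycle and amino acid metabolism, 0.05 for glycolysis and gluconeogenesis and 0.09 for oxidative phosphorylation. The remaining lists of cell functions had -0.0026 for translation factors, 0.08 for proteasome, 0.02 for heat shock and chaperones, 0.06 for endoplasmic reticulum stress and secretory path, 0.0062 for oxidative stress and iron, -0.05 for cell cycle and -0.03 for extracellular matrix and remodelling. In these lists SSR3 at -0.99 and EIF6 at 0.90 at 1 h, ACADM at -0.85 at 30 min, FOXA1 at -1.07 at 3 h, and PSMC3 at 0.91 and IL1RAP at 0.73 at 16 h passed when adjusted over the list alone, and none of these 6 passed over all probes.

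Markers of other cell types were called at no time. At 16 h the medians were 0.22 for monocyte and macrophage, -0.20 for lymphocyte, -0.11 for endothelial cell, 0.18 for fibroblast and stellate cell and 0.15 for erythroid cell, over 7, 5, 6, 7 and 9 genes. The cholangiocyte markers, 3 genes measured with a median of 0.43, and the neutrophil markers, 4 genes with a median of 0.10, were too few to test. CD79A at 15 min had 1.10, PECAM1 at 6 h 0.80, and at 1 h PRTN3 had 0.54 and CSF3R -0.62; these 4 passed when adjusted over the list alone and none passed over all probes.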

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

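The comparison of times whose 3 pairs lie on opposite sides of 0 was fixed in advance, and the exchange of the media within pairs was chosen only after the result was seen. Only the 6 times after T0 were examined. For 9 of the 28 named genes and called lists, all 3 pairs were higher in CM at 1 of these times and all 3 lower at another. The difference was not tested between times that are not adjacent, and in the tests between adjacent late times the smallest adjusted p by limma was 1.00. CFB differed by 1.58 between 16 h (mean 1.47, SD 0.61, n = 3 pairs) and 1 h (mean -0.11, SD 0.09). NFKB1 differed by 1.44 between 3 h (1.22) and 30 min (-0.22). ACTG1 differed by 1.78 between 1 h (1.32) and 15 min (-0.46), and its other probe had -0.23 at 1 h. The remaining genes differed by 1.37 for TMEM126B between 6 h and 15 min, 1.26 for DAPK1 between 15 min and 6 h, 1.14 for CLIP1 between 30 min and 1 h, 1.11 for PDXDC2P-NPIPB14P between 6 h and 3 h, and 1.05 for BDH1 between 15 min and 6 h. For the apoptosis list the median over its genes was taken in each pair. The mean of these medians over 3 pairs differed by 0.36 between 6 h (mean 0.28, SD 0.14) and 16 h (mean -0.07, SD 0.06). Among the 21 named genes 8 had such times after T0. In 100 random exchanges of the media within the pairs after T0 the median was 6 and the highest 13, so this number lies within what chance gives.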

How the results depend on the processing

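The alternatives named neighbour centring, array weights, without the pairs of the least correlated arrays and without the probes with copied values, and all those of the means over 3 times, were chosen only after the results were seen. Counts below are probes called by limma unless named otherwise, the causes were not tested, and no result reversed. Of the counts under all alternatives, 202 stayed within 1.5 times the reported count and 49 moved. A count of 0 that stayed at 0 is included in the 202. Most reported counts were 0, so the 202 say little about how stable the counts above 0 are. At T0, 1 h and 6 h, where 0 were called, leaving out a replicate gave 0 to 1: 1 at T0 without replicate 1, 1 at 1 h without replicate 2 and 1 at 6 h without replicate 3. At 3 h the count was 1 without the dimmest 25% of probes, 1 without the dimmest 50%, 1 with the floor at the 10th percentile and 1 with an intensity trend and robust spread. Array weights gave 42 at 15 min, 1 at 1 h, 12 at 3 h, 5 for the test over all times after T0 and 13 for the mean of 3 h, 6 h and 16 h. The weights ranged from 0.320 for the NCM array of replicate 1 at 1 h to 5.56 for the CM array of replicate 3 at 15 min.

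At 16 h, where 1 was called, the count was 0 with no replicate block, 0 with the values as deposited, 0 with median centring of each array only, 0 with each time fitted alone and 0 for the change minus the change at T0. It was 2 without the dimmest 25% of probes, 7 without the dimmest 50%, 2 with the floor at the 10th percentile, 3 with an intensity trend and robust spread, 7 with neighbour centring and 6 without the pairs of the least correlated arrays. It was 0 to 3 without 1 replicate: 1 without replicate 1, 0 without replicate 2 and 3 without replicate 3. Neighbour centring also gave 1 at 6 h and 2 for the test over all times after T0, for which the trend with robust spread gave 2. The 4 pairs of the least correlated arrays are replicate 2 at T0, replicate 1 at 15 min, replicate 2 at 30 min and replicate 1 at 1 h.

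For the mean of 3 h, 6 h and 16 h, with 6 called, the count was 0 with no replicate block, 1 with the values as deposited, 1 with median centring of each array only, 1 with each time fitted alone, 10 with the trend and robust spread, 1 at a change of at least 1 and 0 for the change minus the change at T0. It was 0 to 2 without 1 replicate: 0 without replicate 1, 0 without replicate 2 and 2 without replicate 3. For NCM over time, with 2 called, it was 1 with the values as deposited, 1 with median centring, 0 without the pairs of the least correlated arrays, 1 without the probes with copied values and 0 to 0 without replicate 1, 2 or 3.

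Of the gene list tests, 9 were called, against 0 with an estimated correlation, 5 with neighbour centring and 1 to 11 without 1 replicate: 11 without replicate 1, 2 without replicate 2 and 1 without replicate 3. The medians of the called lists kept their direction under the alternatives that were run for lists, with 57 no longer past the threshold and 51 on the same side. For named genes 155 stayed on the same side, 26 no longer passed and 1 passed newly. All 26 losses fall on CFB at 16 h and on IL32, PSME1, CFB and IL1R1 in the mean of 3 h, 6 h and 16 h. The other named genes had not passed and had no call to lose, so most of the 155 do not show a stable call. The no replicate block fit ended the calls of the metallothionein and apoptosis lists and of complement in the late mean, and changed none of the other calls of the lists. No table measures signal over background, so how far it limits these counts is open; leaving out dim probes moved only the counts at 3 h and 16 h by over 1.5 times.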

Other observations

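The neighbour centring and all tests here were chosen only after the results were seen, except the test of other probes of STAT5A and STAT5B, which was fixed before its result was known. With the mean deviation of neighbouring probes subtracted on each array, 7 probes were called at 16 h, all higher in CM. Besides CFB (1.40, SE 0.18) they include ORM1 (1.16, SE 0.21), IRAK2, a kinase gene of interleukin-1 receptor signalling (1.40, SE 0.21), TMSB10, thymosin beta 10 (1.03, SE 0.16), NDUFB7, a subunit of respiratory complex I (1.00, SE 0.15), and 2 probes that name 2 genes each. At 6 h the 1 called probe was IL32 (1.21, SE 0.18). In the mean of 3 h, 6 h and 16 h the 8 called probes include IL32 (0.91), ABCA1 (0.85), PSME1 (0.68), CFB (0.68), PSMB10, a subunit of the immunoproteasome (0.67), and LAPTM5, a lysosomal membrane protein gene (0.58). These genes were named after their values were seen. Over 6 sizes of the neighbourhood the count at 16 h was 6 to 8. In simulated data with a gradient 75 changed probes were recovered without the centring and 97 with it, which also called 4 unchanged probes. Without a gradient 103 were recovered. The simulated gradient ran over the rows of the same assumed grid that the centring uses. The simulation therefore does not test that layout or the added calls on the real arrays.

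Of the 10 splits of the 6 arrays at a time into groups of 3, the splits are too few for a share under 0.05. At 16 h 6 of 10 splits called at least 1 probe, the real value, with 2 the highest of the others. At the other times the real value is 0, which every split must reach, so 10 of 10 splits gave as many and this decides nothing. The highest other counts were 988 at T0, 388 at 15 min, 3 at 30 min, 97 at 1 h, 14 at 3 h and 19 at 6 h. The large counts come from splits that part only 1 of the 3 pairs, which rest on that pair alone because the pair is a block. Counts that large point to a structure of the samples, whose cause was not tested. Among the 4 splits that part 3 pairs, the real one included, the highest other count was 1 at T0, 0 at 15 min, 0 at 30 min, 1 at 1 h, 1 at 3 h, 1 at 6 h and 2 at 16 h. For the differences between 1 h and 3 h, 3 h and 6 h, and 6 h and 16 h, 10 of 10 splits of the 6 pairs gave as many as the real 0, with 0, 0 and 1 the highest of the others. Every split must reach 0 here too, so the share decides nothing. For the test over all times after T0, 100 of 100 exchanges of the media gave as many as the real 0 (highest other 1), which every exchange must reach, so this decides nothing about chance. For the mean of 3 h, 6 h and 16 h, 1 of 100 exchanges gave as many as the real 6, the real one itself, with 1 the highest of the others. The exchanges do not repeat the choice of this mean, which was made after seeing the data, so they do not exclude chance. They also treat the 9 pairs as independent, though these come from 3 experiments. For the mean of 15 min, 30 min and 1 h, 100 of 100 gave as many as the real 0 (highest other 2), which again decides nothing. For NCM over time, 12 of 100 permutations of the times gave as many as the real 2, with 369 the highest of the others, which points to a structure of the arrays, so chance is not excluded. With the replicate as a block and the times permuted within experiment numbers, 3 of 100 gave as many as the same 2, with 44 the highest of the others, so the outcome depends on the block.

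CM against NCM differences of probes with adjacent numbers went together, with a correlation across probes of 0.485 at T0 and 0.150 to 0.291 at later times; probes are not independent replicates. Shared genes are argued against as the whole cause, since adjacent probes that name different genes had a correlation of 0.56 at T0. A response to CM alone is also argued against, since every T0 pair showed the pattern, the lowest at 0.189 against at most 0.021 for shuffled probes. A position effect on the array or in the wells remains a candidate explanation: at T0 the correlation was 0.471 for probes 1 grid row apart and -0.10 for probes 8 grid rows apart. With neighbour centring the correlation at T0 was 0.111.

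In both media, STAT5A probe 10003 was higher by 3.97 at 30 min (SE 0.37) than at the other times, on all 6 arrays of the time. STAT5B probe 5869 was higher by 2.63 at 1 h (SE 0.16), also on all 6 arrays. So was probe 959, which names 3 genes and was not tested further, by 1.93 at 6 h. Against these 3 probes permuted times gave a median of 0 and a highest of 47. At T0, 15 min, 3 h and 16 h STAT5A probe 10003 carries values equal to those of probe 1178. Its 3.97 and SE therefore rest on a mixed baseline. At 1 h and 6 h, with values not equal to another probe's, its NCM means were -2.63 and -2.47. Probe 959 carries values equal to those of probe 7486 at 15 min. For the STAT5 probes the arrays of other times in the same array clusters lay lower. The smaller gap between the lowest array of the time and the highest array of another time in its clusters was 0.91. A gap above 0 follows from the pattern itself, in which all 6 arrays lie above those of every other time. It is therefore no separate test of a shift of the array clusters. For a change of the gene's mRNA, a bound of 1 was set in advance for the other probes of either gene. Their largest change was 0.20 (SE 0.17), under that bound, which argues against such a change as far as those probes measure it. A condition that was not part of the bound asked that probes of 1 gene go together. It was not met, since their deviations over the times correlated at only 0.11. That correlation covers 3200 pairs of probes, whether or not their genes changed. It does not show what the STAT5 probes would miss, and a change of the mRNA is not excluded. Values of another probe in the row stay open as copies that were not exact, since the number of probes with equal values at the high time was 0 for STAT5A and 0 for STAT5B; the copies of STAT5A probe 1178 lie at 4 other times. Material shared by the 6 arrays of 1 time also stays open: the smaller number of arrays of the time above all others was 6, which it needs, but an effect of the time itself would give the same.

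The 42 arrays fell into 4 clusters of 10, 12, 6 and 14 arrays. Time is argued against as the whole cause, since 0 of 7 times had all their pairs in 1 cluster. For experiment number the same count was 0 of 3. However, 3 numbers cannot each fill 1 of 4 clusters, so that rule could not be met in full. Mixed clusters argue against experiment number as the whole cause: 1 held 1 pair of S1, 2 of S2 and 2 of S3, and another held 3, 1 and 2. As part of the cause both stay open (permutation tests of the clusters with 100000 resamples, p = 0.773 and 0.0850): 1 cluster held 3 pairs, all of S1, and the largest held 0 of S1, 4 of S2 and 3 of S3. Preparation of each pair stays open, since 21 of 21 pairs had both arrays in 1 cluster, and the labels give no date or batch that could separate it from the measurement of the arrays.

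Identical values on all 6 arrays of a time occurred in 34 sets of 2 probes, 36 probes in all. The sets numbered 6 at T0, 7 at 15 min, 4 at 30 min, 4 at 1 h, 7 at 3 h, 2 at 6 h and 4 at 16 h, and 0 pairs of probes were equal over all arrays. They represent 16 genes, among them MT2A, MT1G, MT1E, MT1X, C8A, C8B, C4BPA, F12, CEBPB, FOS and FOXA1. Changes measured by different probes of 1 gene correlated at 0.02 to 0.16 over 3221 pairs of probes at the single times.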
